A study of Mus musculus with 8 samples.

How the data were processed

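RNA was measured on two-colour Agilent whole mouse genome arrays, 4 with sorted GFPhi and GFPlo cells and 4 with Ascl2-deleted and control epithelium. Per the labels' protocols, RNA was isolated with Trizol and labelled by linear amplification. Per the file headers, the arrays were quantified with Agilent Feature Extraction 9.5.3.1 under protocol GE2-v5_95_Feb07, and probe positions are those of mouse build mm8 (NCBI36). The scanner files hold, per the file headers, spot intensity values on a linear scale, as the mean foreground and the median local background of each channel. They also hold, per the file headers, processed signal intensities that Feature Extraction had background-subtracted and dye-normalized, and their log10 ratio of Cy5 over Cy3. The deposited series matrix holds log2 ratios of the same arrays, already turned so that each is deleted over control or GFPhi over GFPlo. Each of its columns correlated with the scanner's log ratio at an absolute r of 0.972 or more once turned, and its medians ran from -0.0248 to 0.0306. Whether the authors centred these columns, and which spots they left out, stays unknown. The scanner files of day 5 hold values rounded to 3 significant digits and gene symbols turned into dates by a spreadsheet, so annotation for those arrays was taken from the day 3 files by feature number.

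Each array has 45018 features, of which 43379 spots are not controls and 1639 are controls. The background was corrected with normexp (offset 50) over all spots, control spots then had weight 0 in a loess fit within each array, and spots with a non-uniformity or population outlier mark were left out. The log2 ratios were turned to GFPhi over GFPlo or deleted over control by the dyes the labels state. Spots of 1 probe were averaged, giving 41174 probes. Through accessions in RefSeq's gene table, used for names alone, 23374 probes were named, 6733 had a current symbol in the file and 2919 an older one, and 8148 kept the file's own name, for 27573 names. That table is built on assembly GRCm38.p6 and none of its coordinates were used. A gene was represented by its brightest probe. Among the 42 named or listed genes with more than 1 probe above background in both comparisons, probes differed in sign for Ier2 and Apob in the sorts and for Ier2 and Nfe2l2 in the deletion. Where probes above background in the deletion alone also counted, signs differed there for further genes, such as Apob, Cd8b1 and Id4.

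The 2 dye-swapped arrays of an RNA pair share both RNA extracts and were averaged to 1 replicate. All 4 RNA pairs were fitted together with lmFit and eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0 and version 1.17.8 of data.table), with 1 coefficient per comparison and 1 shared estimate of the spread. The eBayes prior had 1.99 degrees of freedom and an SD of 0.156. The median SD between RNA pairs was 0.0808 for the sorts and 0.224 for the deletion days, whose difference in time adds to that spread. The day difference was fitted with a coefficient for each day, so that its spread comes from the sorts alone. A gene was tested where its probe was well above background on every array of at least 1 of the 2 RNAs, which left 10385 genes in the sorts, 15829 in the deletion and 10263 in both. For genes not tested in the sorts the ratios of the 2 sorts lay closer together, with a median SD of 0.0460 against 0.0808, so their standard errors in the deletion and day tests are low. Adjusted p values are Benjamini-Hochberg values with a threshold of 0.05, two-sided. Because mice were pooled within a sort and the labels name no separate animals for the deletion pairs, p values measure the spread between these pools or extracts.

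The gene lists of cell types and pathways, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. They were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 5 tested genes, and again with an estimated correlation. For the sorts and the deletion, that estimate rests on the spread left among the 4 RNA pairs, which includes the difference between the deletion days. For the day difference it rests on the sorts alone. Where no probe of a gene was well above background in a group, only a bound on its ratio is given. The genes named follow a rule fixed in advance. Ascl2 and Lgr5 come first. Per comparison, the 12 largest in each direction past the test with 1 sign on all 4 arrays are named, and where fewer pass, the largest with 1 sign and at least 2-fold on each array, said not to pass. Each list gives up to 4 members with the smallest p, besides Olfm4, Muc2, Lyz1, Chga, Dclk1, Sis, Mki67 and Axin2. The overlap names up to 12 genes, and the day difference 6 in each direction. Names that are accessions, clones or predicted genes stay in the counts and are not named, and some genes that the rule names are not reported here. Cd34, Ccdc80, Fstl1, Col6a3, Col4a1, Xist and the Y-linked genes are outside this rule and were chosen to test explanations.

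The procedure was tested on simulated data built on the spread of each fit. Of 100 genes changed 2-fold and 100 changed 4-fold among 10385, the sort comparison recovered 30 and 83, with 5 calls among unchanged genes. Among 15829 genes the deletion comparison recovered 13 and 88, with 7 such calls, and the day difference 96 and 100, with 109. Of the genes at least 2-fold on each array, 27 of 124 in the simulated sorts and 36 of 138 in the simulated deletion were unchanged. The simulation gave all 4 RNA pairs of a gene 1 spread. In the data the median SD was 0.0808 between the sorts and 0.224 between the days, so the shares recovered may differ there. Each slide held the 2 arrays of 1 RNA pair in 1 scan, so the slide and the RNA pair cannot be told apart, and the fit with the RNA pair as a random block is also the fit with the slide as one. The alternatives covered background correction, the scanner's processed signals, the series matrix, median centring, outlier marks, the filter on dim probes, the probe of a gene, dye orientation, the samples in the fit, the variance model, thresholds, set sizes and leaving out each RNA pair.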

Results

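Gene expression was compared on 8 two-colour arrays carrying probes for the mouse transcriptome, 4 for each of 2 comparisons. The first set RNA of GFPhi cells against RNA of GFPlo cells, both sorted from the intestine of mice in which the green fluorescent protein is made from the Lgr5 gene, a marker of the dividing stem cells at the base of the crypts. There were 2 sorts, each pooling 3 mice. The second set epithelial RNA of Ah-Cre mice with both copies of Ascl2 floxed against RNA of Ah-Cre control mice with 1 floxed copy, at 3 and at 5 days after Cre induction. Each of the 4 RNA pairs was hybridised to 2 arrays with the dyes swapped, and these 2 arrays counted as 1 replicate, so each comparison had n = 2 RNA pairs. Nothing in the sources used here says how many animals stand behind each deletion pair. Between 55.0% and 66.9% of spots were well above background per channel on the deletion arrays, and between 35.5% and 44.6% on the sort arrays. The number of arrays limits the precision of every value. The comparisons ask which genes mark Lgr5 stem cells, which genes depend on Ascl2, and whether these are the same genes.

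Ascl2, which encodes a basic helix-loop-helix transcription factor, was lower in the deleted epithelium on all 4 arrays. Its log2 ratios to control were -1.36 and -1.30 on day 3 and -1.34 and -1.29 on day 5. The mean was -1.32 ± 0.0083 (SD, n = 2 RNA pairs), a level 2.50-fold lower, with a standard error of 0.08 and a limma adjusted p of 0.238, which did not pass the threshold of 0.05. Among the sorted cells Ascl2 was higher in GFPhi on all 4 arrays, with log2 ratios of 0.45 and 0.27 in sort 1 and 0.33 and 0.40 in sort 2, a mean of 0.36 or 1.29-fold (limma adjusted p = 0.650). The probe lies on chromosome 7 at 142777924 to 142777983, minus strand, in mouse build mm8. Which part of the gene the floxed allele removes is not given in the sources used here, so whether this probe lies within it is open. Lgr5, the gene that drives the sorted reporter, was higher in GFPhi cells on all 4 arrays, at 1.995 and 2.21 in sort 1 and 1.74 and 1.48 in sort 2. Its mean of 1.85 ± 0.35 (SD, n = 2 sorts) is 3.62-fold (limma adjusted p = 0.627). In the deleted epithelium Lgr5 was lower on all 4 arrays, with means of -0.52 on day 3 and -0.88 on day 5 (limma adjusted p = 0.475). This Lgr5 probe lies on chromosome 10 at 114855901 to 114855960, minus strand, in mm8, and the other Lgr5 probe was not above the signal filter in either comparison.

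GFPhi cells held more RNA of crypt base stem cell genes and less RNA of goblet and enteroendocrine cell genes than GFPlo cells. Of 24 measured crypt base stem cell genes, Lgr5 among them, 23 had a log2 ratio above 0, with a list median of 0.75. All 17 measured goblet cell genes and all 24 measured enteroendocrine genes had a ratio below 0, with medians of -0.97 and -0.46. The enteroendocrine median was -0.78 in sort 1 and -0.17 in sort 2. With an estimated correlation the crypt base stem cell, goblet and enteroendocrine lists did not pass (camera adjusted p = 0.419 each). Genes of the cell cycle were near equal, at a median of 0.05 over 38 genes. Single hormone and mucus genes were lower in GFPhi too, with Cck at 4.40-fold and Agr2 at 4.14-fold lower.

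Besides Lgr5, 2 genes were at least 2-fold higher in GFPhi on each of the 4 arrays. They were Ephb3, an ephrin receptor gene that positions cells along the crypt, at 1.27 (2.41-fold, SE 0.21), and Acot1, an acyl-CoA thioesterase gene, at 1.31 (2.48-fold, SE 0.30). Neither passed the limma test (adjusted p of 0.650 and 0.709). In the other direction 14 genes were at least 2-fold lower on each array and none of them passed in the joint fit. Those of hormone cells were Cck (cholecystokinin) at -2.14, Chgb and Chga (granins of secretory granules) at -2.06 and -1.89, and Sct (secretin) at -1.94. Those of mucus cells were Agr2, a protein disulfide isomerase gene, at -2.05, Tff3 (trefoil factor 3) at -1.93, Clca1 at -1.88 and Zg16 at -1.42. Guca2a, which encodes guanylin, was at -1.96, Dmbt1 at -1.42, Rbp7 at -1.21 and Anxa13 at -1.20. The standard errors of these 12 genes and Muc2 ran up to 0.58, and their limma adjusted p values were 0.627 or more. With the sorts fitted alone, so that the deletion days do not enter the spread, all 14 passed, as did Lgr5, Ephb3 and Acot1. Their limma adjusted p values in that fit ran from 0.0047 to 0.0150. Muc2, the main secreted mucin of the intestine, was at -1.88 in sort 1 and -1.05 in sort 2.

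Within the crypt base stem cell list, 13 members rose when p values were adjusted over the list alone, against 0 adjusted over all genes. Camera gave the list an adjusted p of 6.57e-26 with a preset correlation between genes, and an adjusted p = 0.419 with an estimated correlation. This list was in part proposed by this study or from cells sorted the same way, so it is not independent evidence of direction. Lgr5, whose rise follows from the sort itself, is among the 13 and among the 10 Wnt/beta-catenin targets given below. Among its members were Sp5 at 1.30, Ephb3 at 1.27, Cdk6 at 0.94, Olfm4 at 0.92 and Sox9 at 0.84. Slc12a2, a sodium, potassium and chloride cotransporter gene, was at 0.63 and Axin2 at 0.15. Gkn3, a gastrokine gene outside the list, was at 1.36. Of 21 measured Wnt/beta-catenin targets, 20 were higher in GFPhi with a median of 0.50, and 10 rose adjusted over the list alone (camera adjusted p = 6.90e-19). Reserve stem cell genes were higher in 5 of 6, with a median of 0.14 and 1 member past the test adjusted over the list alone (camera adjusted p = 0.0091). These 2 lists share members with the first, and their adjusted p with an estimated correlation was 0.419 and 0.430. MHC class II genes were higher in 7 of 7 at a median of 0.46, with Cd74 at 0.46 and H2-DMa at 0.37, and 0 passed adjusted over the list alone (camera adjusted p = 9.16e-06, adjusted p = 0.430 with an estimated correlation). T cell and myeloid markers were at medians of 0.02 and -0.08 in the same comparison.

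The goblet cell list fell in GFPhi with 12 of its 17 members past the test adjusted over the list alone (camera adjusted p = 4.71e-23). For the enteroendocrine list this number was 5 of 24 (camera adjusted p = 1.53e-18), and for both lists the adjusted p was 0.419 with an estimated correlation. Enteroendocrine genes differed in size between the sorts, at medians of -0.78 in sort 1 and -0.17 in sort 2, with the hormone gene Pyy at -2.41 and -0.04. Tuft cell genes were lower in 9 of 10 at a median of -0.40, made up of -0.76 in sort 1 and -0.04 in sort 2 (camera adjusted p = 0.0163). Secretory progenitor genes were lower in 7 of 9 at -0.27, made up of -0.39 and -0.06 (camera adjusted p = 0.0236), and both lists had an adjusted p of 0.767 with an estimated correlation. Neither passed without sort 1, and with either deletion day left out of the fit the secretory progenitor list did not. The brightest probe of the tuft cell kinase gene Dclk1 was well above background on 0 of 4 arrays in GFPhi and on 1 of 4 in GFPlo and was not tested, while a dimmer Dclk1 probe that passed the signal filter was at -1.36 in sort 1 and -0.10 in sort 2. Enterocyte genes were lower in 21 of 27 at -0.23, made up of -0.29 and -0.14 (camera adjusted p = 0.000637), and their adjusted p was 0.775 with an estimated correlation. Sis, the sucrase-isomaltase gene of the brush border, was at -0.30.

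Genes of protein folding in the endoplasmic reticulum were lower in GFPhi in 16 of 17, with a median of -0.31 and Xbp1 at -0.49 (camera adjusted p = 1.21e-08). Antimicrobial and acute phase genes were lower in 7 of 8 at -0.31, made up of -0.35 in sort 1 and -0.15 in sort 2 (camera adjusted p = 0.0468), and did not pass without sort 2. Both had an adjusted p of 0.430 with an estimated correlation. Cholesterol synthesis genes were lower in 19 of 20 at -0.17, with Msmo1 at -0.71 and 2 members past the test adjusted over the list alone (camera adjusted p = 3.16e-08). Targets of the aryl hydrocarbon receptor were lower in 4 of 5 at -0.22, made up of -0.35 and -0.21 (camera adjusted p = 0.0048), and for both lists the adjusted p was 0.419 with an estimated correlation. Paneth cell genes were lower in 21 of 23 at a median of -0.16, made up of -0.36 in sort 1 and 0.0020 in sort 2, but did not pass (camera adjusted p = 0.0923), with the lysozyme gene Lyz1 at 0.01. Among 38 cell cycle genes the proliferation marker Mki67 was at 0.25.

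By limma, 521 of 10385 genes tested had an unadjusted p under 0.05, 260 of them higher and 261 lower in GFPhi. If no gene changed, a share of 0.05 would have such a p, which is close to the share seen. Of the genes tested, 0 passed at an adjusted p under 0.05. The count was 65 with the sorts fitted alone, 117 with either deletion day left out of the joint fit, and 15 with all 8 arrays fitted and the RNA pair as a random block. One sign on all 4 arrays was seen for 33.8% of genes, against 19.2% if the 2 sorts were independent of each other and each kept its own share of genes with 1 sign on both dye-swapped arrays. The 3 genes higher and 14 lower by the 2-fold rule became 44 and 127 on the scanner's own processed signals, 24 and 59 on the series matrix values, and 9 and 33 without background subtraction.

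**Figure D1:**
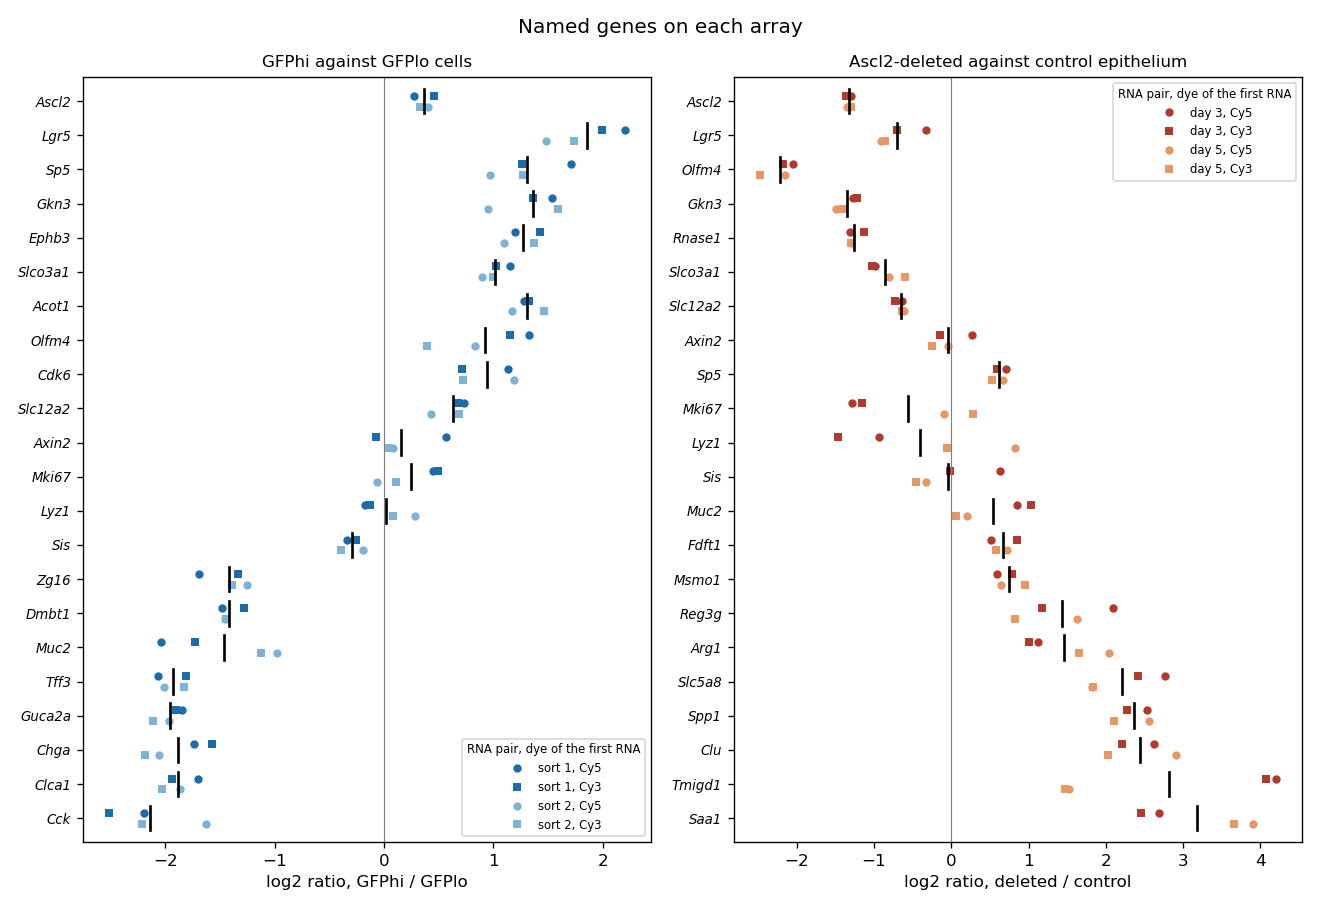
Log2 ratios of named genes on each array, with GFPhi over GFPlo cells on the left and Ascl2-deleted over control epithelium on the right. Each point is 1 array, coloured by RNA pair and shaped by the dye of the first RNA, and each black bar is the mean of the 2 RNA pairs; Ascl2 lies near -1.32 on all 4 deletion arrays, and Lgr5 lies above 0 on all 4 sort arrays.

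Deletion of Ascl2 went with lower levels of crypt base stem cell genes and higher levels of acute phase and cholesterol synthesis genes. Of 24 crypt base stem cell genes, Ascl2 itself included, 21 had a log2 ratio below 0, at a list median of -0.59. Olfm4, which encodes a secreted glycoprotein of crypt base cells, was 4.64-fold lower. Spp1 (osteopontin), Clu (clusterin) and Saa1 (serum amyloid A) were 5.16-fold, 5.44-fold and 9.03-fold higher. All 21 cholesterol synthesis genes were higher, at a median of 0.41, and all 42 cell cycle genes had a mean ratio below 0, at a median of -0.56 that came from day 3 alone (-1.10, against 0.03 on day 5). Antimicrobial and acute phase genes were at medians of 0.29 on day 3 and 1.22 on day 5. With an estimated correlation the crypt base stem cell, acute phase and cholesterol synthesis lists did not pass (camera adjusted p = 0.621 each).

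At least 2-fold higher on every one of the 4 deletion arrays were 12 genes, and 10 were at least 2-fold lower; none passed the limma test. The higher ones were Saa1 at 3.17 (SE 0.31, adjusted p = 0.365), Tmigd1 at 2.82, Saa2 at 2.51, Clu at 2.44 (SE 0.15, adjusted p = 0.238), Spp1 at 2.37 (SE 0.08, adjusted p = 0.113) and Slc5a8, a monocarboxylate transporter gene, at 2.21. Slc52a3, a riboflavin transporter gene, was at 1.79, the immunoglobulin segment Igh-VJ558 at 1.54, Tmem117 at 1.51, Arg1 (arginase 1) at 1.46 and Wwc2 at 1.29. The lower ones besides Ascl2 were ccdc198 at -2.26, Olfm4 at -2.21 (SE 0.18, limma adjusted p = 0.322), Xlr3c at -1.76, the angiopoietin gene Angpt2 at -1.58, the MAP kinase phosphatase gene Dusp4 at -1.48, Gkn3 at -1.34 (SE 0.10, limma adjusted p = 0.294), Rnase1 at -1.26 and the efflux transporter gene Abcc2 at -1.08. Xlr3c was well above background on 3 of 4 arrays in deleted epithelium. The Olfm4 probe lies on chromosome 14 at 78755746 to 78755805, plus strand, in mm8. Several of these genes had like ratios on both days: Olfm4 was at -2.12 and -2.31, Gkn3 at -1.24 and -1.44, Clu at 2.42 and 2.47, and Spp1 at 2.40 and 2.33. Others did not, such as Tmigd1 at 4.14 and 1.5 and Saa2 at 3.76 and 1.27. The brightest Saa1 probe was at 2.57 and 3.78 and another one at 4.13 and 0.996. Other Igh-VJ558 probes above background ran from 1.56 and 1.64 down to -0.02 and 0.05 on day 3 and day 5, most of them lower than the brightest. A dimmer Dusp4 probe above background was at -0.53 on both days, against -1.28 and -1.67 on the brightest.

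In the crypt base stem cell list, 10 members fell and 1 rose adjusted over the list alone, against 0 adjusted over all genes (camera adjusted p = 8.04e-09). The median was -0.76 on day 3 and -0.38 on day 5. Part of this list was proposed by this study or from cells sorted the same way, so it is not independent evidence of direction. Ascl2, the deleted gene, is among the 10 and is also 1 of the 2 Wnt/beta-catenin targets past the test given below. Its fall says nothing of the other members. Members lower on both days included Slc12a2 at -0.65 and Cdk6 at -0.78, and Ephb3 was at -0.80. Sp5, a Wnt target gene, was higher at 0.62 and Axin2 was at -0.04. Wnt/beta-catenin targets were lower in 22 of 25 at -0.32, made up of -0.54 on day 3 and -0.17 on day 5, with 2 past the test adjusted over the list alone (camera adjusted p = 0.000225). Reserve stem cell genes were lower in 6 of 7 at -0.40, made up of -0.53 and -0.11 (camera adjusted p = 0.0134). The adjusted p of these 3 lists was 0.621 with an estimated correlation. Cell cycle genes had 0 members past the test adjusted over the list alone (camera adjusted p = 4.19e-10), with Mki67 at -1.22 on day 3 and 0.09 on day 5 and Rrm2, a ribonucleotide reductase gene, at -1.20 and -0.32. Paneth cell genes were lower in 23 of 25 at -0.50, made up of -1.28 on day 3 and 0.13 on day 5, with Lyz1 at -1.20 and 0.39 and Pnliprp2 at -0.83 and -0.95 (camera adjusted p = 9.32e-05, 1 member past the test adjusted over the list alone). Secretory progenitor genes were lower in 8 of 11 at -0.22, with medians of -0.06 on day 3 and -0.11 on day 5 (camera adjusted p = 0.0351). Without day 3 the cell cycle and Paneth cell lists no longer passed, and the reserve stem cell and secretory progenitor lists did not pass with either day left out. For the cell cycle, Paneth cell and secretory progenitor lists the adjusted p was 0.625 with an estimated correlation.

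Cholesterol synthesis genes rose, at medians of 0.38 on day 3 and 0.65 on day 5, with 12 of 21 past the test adjusted over the list alone and Msmo1 at 0.74 and Fdft1 at 0.67 (camera adjusted p = 2.90e-13). Antimicrobial and acute phase genes were higher in 12 of 17 at a median of 0.87, made up of 0.29 on day 3 and 1.22 on day 5, with 2 past the test adjusted over the list alone and Reg3g, a bactericidal lectin gene, at 1.43 (camera adjusted p = 0.0058). Genes of regenerating epithelium were higher in 11 of 15 at 0.25, made up of -0.11 on day 3 and 0.39 on day 5, with 2 past the test adjusted over the list alone (camera adjusted p = 0.0066). Immediate early and heat shock genes were higher in 18 of 24 at 0.32, made up of 0.52 and 0.08 (camera adjusted p = 0.0134). Interferon response genes were lower in 22 of 28 at -0.29, made up of -0.25 and -0.30, with Mx2 at -0.53 and Ifi44 at -1.55 (camera adjusted p = 0.0081). Without day 5 the acute phase, regenerating epithelium and interferon lists no longer passed, and without day 3 the immediate early list did not. All 5 of these lists had an adjusted p of 0.621 with an estimated correlation.

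Lists of stroma, immune cell, MHC class II and pancreas genes moved with these groups. MHC class II genes were also higher in sorted GFPhi cells, at a median of 0.46, so here they cannot be read as markers of cells other than epithelium. Stroma and smooth muscle genes were higher in 22 of 23, at medians of 0.06 on day 3 and 1.42 on day 5, with 0 past the test adjusted over the list alone (camera adjusted p = 2.35e-05). Fn1 (fibronectin) was at 0.68 and 2.26, with 1 of 4 control arrays well above background, and Mgp (matrix Gla protein) at 0.28 and 3.18. T cell genes were higher in 24 of 27, at medians of 0.94 on day 3 and -0.04 on day 5, with the surface receptor gene Cd5 at 0.71 and 1 member past the test adjusted over the list alone (camera adjusted p = 6.65e-05). MHC class II genes were higher in 7 of 7 at 1.05 and 0.10, with Cd74 at 1.48 and 0.26 and 2 members past the test adjusted over the list alone (camera adjusted p = 0.000994). B and plasma cell genes were higher in 5 of 6 at 0.43, made up of 0.72 on day 3 and 0.06 on day 5, with the J chain gene Jchain at 1.64 and 0.80 and 2 past the test adjusted over the list alone (camera adjusted p = 0.0181). Myeloid genes were higher in 18 of 23 at 0.12, made up of 0.16 and 0.10 (camera adjusted p = 0.0134). Pancreas acinar genes were lower in 8 of 11 at -0.09, made up of -0.12 and -0.08, with 3 lower and 1 higher past the test adjusted over the list alone (camera adjusted p = 0.0428). Without day 3 the T cell, MHC class II and B and plasma cell lists no longer passed, without day 5 the stroma and myeloid lists did not, and the pancreas list did not pass with either day left out. The adjusted p of these lists was 0.621 to 0.625 with an estimated correlation.

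The enterocyte, tuft, goblet and enteroendocrine cell lists did not pass in the mean of both days. Enterocyte genes were at 0.19 (camera adjusted p = 0.104), made up of 0.75 on day 3 and -0.37 on day 5, with Sis at 0.31 and -0.40. Tuft cell genes were at 0.12 (camera adjusted p = 0.691), made up of 0.65 and -0.36, with Dclk1 at 0.71 and -0.58, where 2 other probes gave like values and a dimmer one 0.08 and 0.28. Goblet cell genes were at 0.05 (camera adjusted p = 0.841), made up of 0.14 and -0.15, with Muc2 at 0.94 and 0.13, Zg16 at 1.90 and -0.39, Tff3 at 1.24 and -0.30 and Clca1 at 1.38 and -0.22. Enteroendocrine genes were at -0.09 (camera adjusted p = 0.110), made up of 0.11 and -0.20, with Chga at 0.21.

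By limma, 1522 of 15829 genes tested had an unadjusted p under 0.05, 775 higher and 747 lower. The share seen is above the 0.05 that would have such a p if no gene changed. Of the genes tested, 0 passed at an adjusted p under 0.05. The count was 0 with the days fitted alone, 129 with all 8 arrays fitted and the RNA pair as a random block, 1181 without day 3 and 6070 without day 5, where the lone day is assumed to vary like the sorts. One sign on all 4 arrays was seen for 25.9% of genes, against 26.1% if the 2 days were independent of each other in the same sense. The 12 genes higher and 10 lower by the 2-fold rule became 50 and 35 on the scanner's processed signals, 29 and 23 on the series matrix values, 182 and 113 without day 3, and 274 and 271 without day 5.

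**Figure D2:**
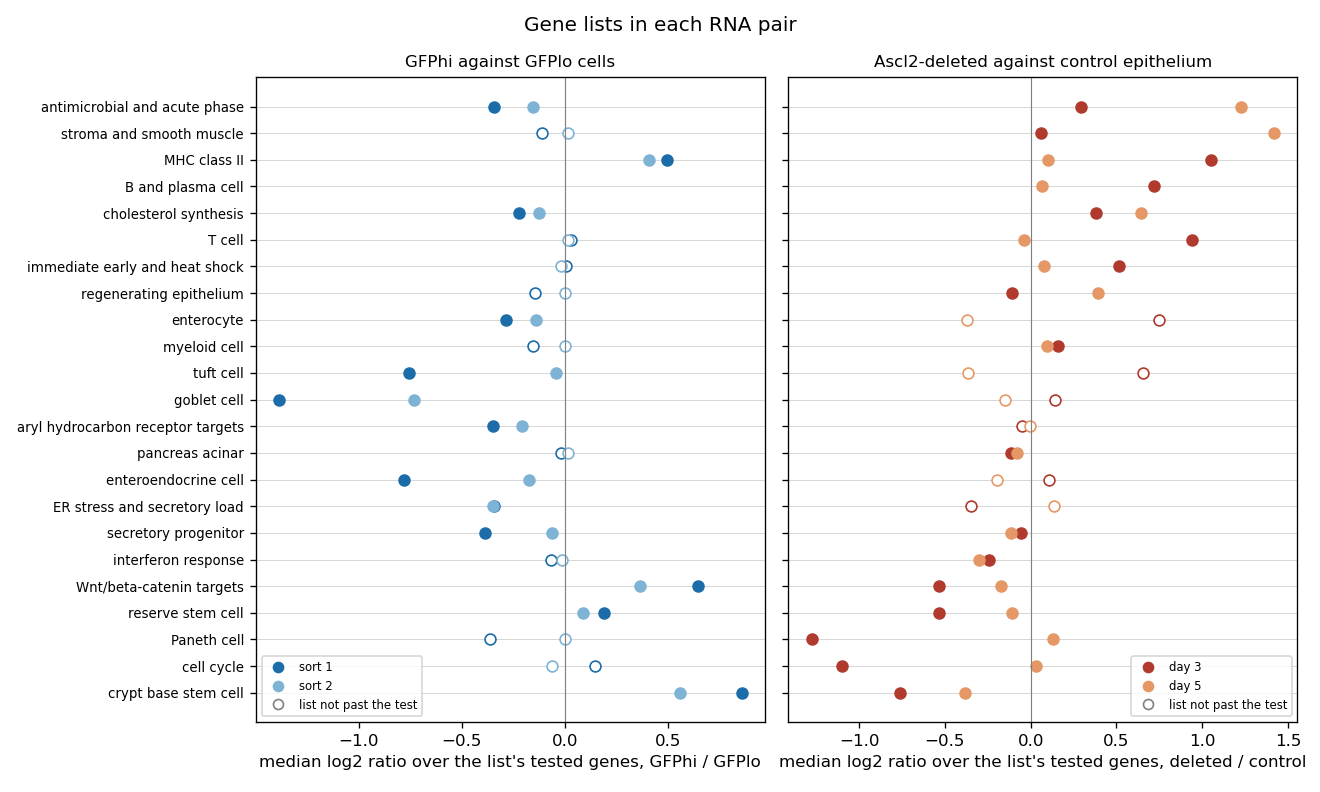
Median log2 ratio over the tested genes of each list that passed camera in at least 1 comparison, with the 2 sorts on the left and the 2 deletion days on the right. Each point is 1 RNA pair and open points mark lists that did not pass with the preset correlation; crypt base stem cell genes lie at 0.86 and 0.56 in the sorts and at -0.76 and -0.38 after deletion.

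The deletion ratios of day 3 and day 5 had little in common across genes. Some cryptdin-related and collagen genes lay below control on day 3 and far above it on day 5, while the Paneth cell list as a whole had a day 5 median of 0.13. Defcr-rs2 and Defcr-rs10, which encode cryptdin-related peptides, went from -1.83 to 6.06 and from -1.98 to 5.54, and Col3a1, Col1a1 and Col1a2 from -1.07, -0.92 and -0.74 to 5.11, 4.81 and 4.68. Saa3, another serum amyloid gene, went from 0.39 to 5.28. In the other direction were the purine genes Ada (adenosine deaminase), from 4.27 to -1.42, and Slc28a2, a nucleoside transporter, from 3.89 to -1.54.

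Pmp22 went from 3.65 to -1.96, H2-Bl from 3.45 to -1.34, Ly6m from 3.06 to -1.72 and Pdk4, a pyruvate dehydrogenase kinase gene, from 1.84 to -2.36. These 12 genes are the 6 that changed most in each direction, with limma adjusted p values of 0.000778 to 0.0012 for the difference. Among the lists, all 42 cell cycle genes were higher on day 5 than on day 3 relative to control, by a median of 1.13, and 39 rose adjusted over the list alone (camera adjusted p = 2.57e-14). All 37 enterocyte genes were lower, by a median of -0.98, and 31 fell adjusted over the list alone (camera adjusted p = 3.70e-14). Paneth cell genes were higher in 24 of 25 by 1.47 (camera adjusted p = 2.76e-09), and T cell genes lower in 26 of 27 by -0.98 (camera adjusted p = 1.28e-09). Stroma and smooth muscle genes were higher in 18 of 23 by 1.32 (camera adjusted p = 3.59e-05), and tuft cell genes lower in 16 of 17 by -0.96 (camera adjusted p = 0.000779). In all, 7 lists were higher and 6 lower, and 0 were called with an estimated correlation, where their adjusted p was 0.834 to 0.863.

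With limma, 4410 of 15829 genes differed between the days, 2454 higher and 1956 lower on day 5. There is 1 RNA pair per day and no replicate of a day, so the test takes its spread from the sorts and says only that the 2 pairs differ by more than the sorts did. The count was 72 on the scanner's processed signals (51 higher and 21 lower) and 0 with median centring in place of loess, where 2511 had an unadjusted p under 0.05. It was 1103 on the series matrix values (736 higher and 367 lower), 2148 with the RNA pair as a random block, 2108 with a normexp offset of 10, 2783 and 2716 with the arrays of 1 dye orientation, and 2427 over genes tested in both comparisons, an alternative chosen after seeing the data. Across 10263 genes, which are not independent replicates, the ratios of the 2 days correlated with Pearson's r of -0.0273 and Spearman's rho of -0.0523, while the dye-swapped arrays of 1 pair correlated at 0.854 on day 3 and 0.756 on day 5. Opposite signs on the 2 days were seen for 51.5% of genes.

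**Figure D3:**
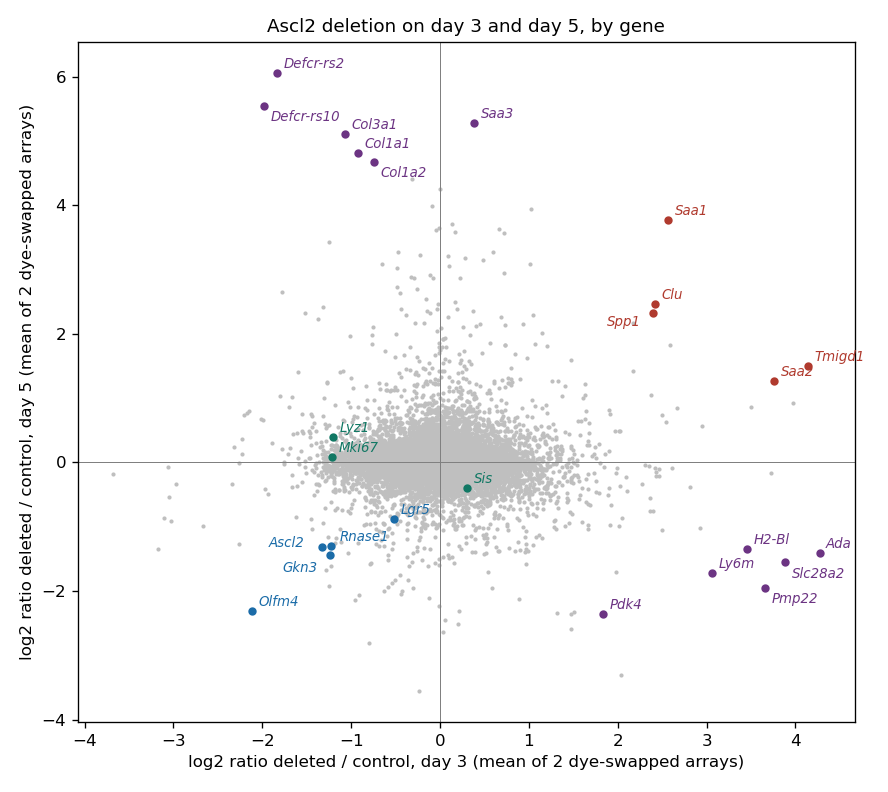
Log2 ratio of deleted over control epithelium on day 3 and on day 5, each the mean of 2 dye-swapped arrays and each point a gene tested in the deletion comparison. Ascl2, Olfm4 and Gkn3 lie below 0 and Spp1, Clu and Saa1 above 0 on both days, while Defcr-rs2 lies at -1.83 and 6.06 and Ada at 4.27 and -1.42.

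Genes that were high in GFPhi cells tended to be lower in Ascl2-deleted epithelium. Of the 100 genes highest in GFPhi, 74 were lower after deletion against 55.0% of all genes, with a median log2 ratio of -0.33, a level 1.26-fold lower. The median was -0.35 on day 3 and -0.27 on day 5, and 52 of the 100 were lower on both days against 27.5% of all genes. Gkn3, Olfm4, Slco3a1, Ephb3 and Cdk6 were high in GFPhi and low after deletion, whereas Rec8, a meiotic cohesin gene, was higher in both, at 1.05 and 1.28.

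Camera on the deletion contrast gave the 100 genes an adjusted p of 3.41e-08 with the preset correlation and an adjusted p = 0.322 with an estimated correlation. On the arrays with the GFPhi or deleted RNA in Cy5 alone, with the 100 genes chosen again on those arrays, the median was -0.04 and did not pass (camera adjusted p = 0.21). The 100 genes lowest in GFPhi had a median of 0.02 after deletion, with 49 of them lower against the same 55.0% (camera adjusted p = 0.746). With 0 genes called in either comparison, no overlap of called genes could be tested. The random block called 2 genes in both. With day 3 or day 5 left out, both tests take their spread from the sorts alone, so genes called in both there do not measure an overlap.

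The genes with the largest ratios in both comparisons, none past the limma test, were named by the smaller of their 2 log2 ratios. Those lower after deletion and higher in GFPhi were Gkn3 at -1.34 and 1.36, Olfm4 at -2.21 and 0.92, Slco3a1 (an organic anion transporter gene) at -0.85 and 1.02, Ephb3 at -0.80 and 1.27, and Cdk6 at -0.78 and 0.94. Lower in both were the retinol-binding protein gene Rbp7 at -1.23 and -1.21, Serpina1d at -0.98 and -0.81, and the amino acid transporter gene Slc7a8 at -0.79 and -0.82. Higher after deletion and lower in GFPhi were Vim (vimentin) at 0.94 and -0.81, S100a6 at 0.82 and -0.85, and Pyy at 0.78 and -1.22. In sort 2 alone Serpina1d and the last 3 were near 0, with Serpina1d at -0.16, Vim at -0.20, S100a6 at -0.15 and Pyy at -0.04. Their deletion ratios also differed in size between day 3 and day 5. These were -0.35 and -1.61 for Serpina1d, 0.35 and 1.53 for Vim, 1.21 and 0.43 for S100a6, and 1.37 and 0.18 for Pyy.

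Among 884 genes with 1 sign on all 4 arrays of both comparisons, 347 were higher in GFPhi and lower after deletion and 99 higher in both, while 161 were lower in both and 277 lower in GFPhi and higher after deletion. Across 10263 genes the 2 log2 ratios correlated with Pearson's r of -0.150 and Spearman's rho of -0.159, and genes are not independent replicates. The r was -0.0535 and -0.0237 on the arrays of 1 dye orientation, -0.03 with median centring and -0.0718 without sort 1.

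**Figure D4:**
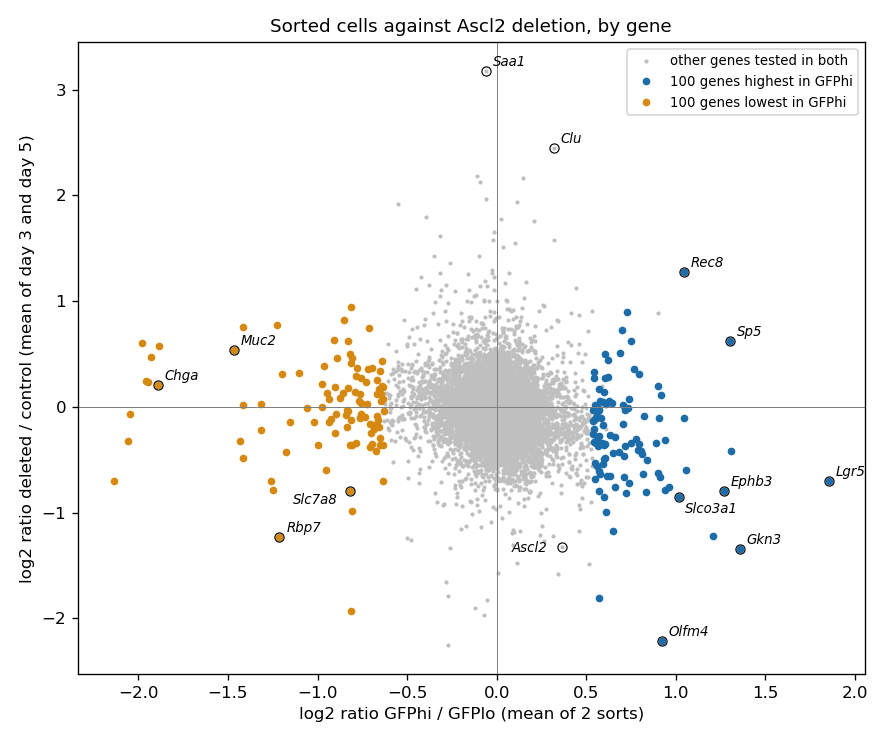
Mean log2 ratio of GFPhi over GFPlo cells against mean log2 ratio of deleted over control epithelium, each point a gene tested in both comparisons. The 100 genes highest in GFPhi are blue and have a median of -0.33 on the deletion axis, and the 100 lowest are orange with a median of 0.02.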

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

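The tests of crypt and villus shares on the fixed lists, of Xist, and of fewer crypts on day 3 and on day 5, were chosen after their results were seen. The other tests of explanations here were fixed before. Standard errors in these tests are taken over the genes of a set. With 1 RNA pair per day they do not measure the spread between preparations.

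The log2 ratio of deleted over control differed between day 5 and day 3 by the limma test for all 12 genes named in that comparison. The difference was 7.89 for Defcr-rs2, 7.53 for Defcr-rs10, 6.19 for Col3a1, 5.73 for Col1a1, 5.42 for Col1a2 and 4.89 for Saa3. It was -5.69 for Ada, -5.61 for Pmp22, -5.43 for Slc28a2, -4.79 for H2-Bl, -4.78 for Ly6m and -4.20 for Pdk4. Of the other genes named in the deletion comparison, the difference passed the test as a higher ratio on day 5 for Mgp at 2.91, ccdc198 at 1.83, Lyz1 at 1.59, Fn1 at 1.58, Mki67 at 1.31, Saa1 at 1.21, Rec8 at 1.10, Xlr3c at 1.003, Rrm2 at 0.88, Arg1 at 0.78, Rbp7 at 0.78, Ephb3 at 0.77, Cdk6 at 0.70 and Tmem117 at 0.61. It passed as a lower ratio on day 5 for Tmigd1 at -2.64, Saa2 at -2.49, Zg16 at -2.30, Clca1 at -1.60, Tff3 at -1.54, Dclk1 at -1.29, Cd74 at -1.22, Ifi44 at -1.18, Jchain at -0.84, Slc5a8 at -0.76 and Sis at -0.70. The difference had the other sign on a second Saa1 probe, at -3.14, and on the dimmest of 4 Dclk1 probes above background, at 0.20 against -1.32 to -1.24 on the others. There is 1 RNA pair per day, and these tests rest on the spread between the sorts.

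By camera with the preset correlation, 13 lists differed between the days. The median difference was 1.47 for Paneth cell genes, 1.32 for stroma and smooth muscle, 1.27 for mast cells, 1.13 for the cell cycle, 1.02 for antimicrobial and acute phase genes, 0.46 for ER stress and secretory load and 0.28 for cholesterol synthesis. It was -1.07 for MHC class II, -0.98 for enterocytes, -0.98 for T cells, -0.96 for tuft cells, -0.77 for B and plasma cells and -0.33 for enteroendocrine cells. With an estimated correlation 0 of the 13 were called.

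Among the sort arrays, Dmbt1 had 1 array far from the others, at -1.29 against -1.48 to -1.45. It was 1 of 45 genes examined by Dixon's test, which flags about 1 in 20 groups by chance.

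Across genes the deletion ratios of day 3 and day 5 did not correlate. All deleted animals being of 1 sex and all controls of the other is argued against, since Xist was well above background on 4 of 4 arrays in both RNAs, at ratios of -0.65 and 0.65; unequal shares of the sexes cannot be told apart, as 7 Y-linked probes, at means of -0.0361 and 0.0294, had 0 signals above background on the deletion arrays. Different shares of crypt and villus cells in the preparations may contribute. In day 5 minus day 3, the fixed enterocyte and cell cycle lists were at -0.98 and 1.13, seen before their test was written. Villus genes outside the fixed lists had a median of -0.82 (SE 0.15, 13 of 14 lower). Proliferative crypt genes outside them were at 0.86 (SE 0.07, 13 of 13 higher). These genes mark the same cells and were measured in the same RNA, so they could be foreseen to follow the fixed lists. Neither set is therefore separate support for this explanation. Different stretches of intestine cannot be told apart from this, as proximal minus distal genes gave 0.13 with an SE of 0.66 (medians -0.17 over 10 genes and -0.30 over 7). A change of cell types with time after the deletion, the biological explanation that the design names, stays open and would give the same shares.

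Genes higher in GFPhi cells were lower after deletion. The 100 genes had deletion medians of -0.29 and -0.31 in the 2 dye orientations. They were chosen on means of dye-swapped arrays, where the dye effect is averaged out. The median of -0.33 over both orientations comes from such means too. These values therefore do not test a dye bias shared by both comparisons. Within 1 orientation such a bias would shift both ratios of a gene the same way, not in opposite ways. With the 100 genes chosen again within 1 orientation, the median was -0.04 with the GFPhi or deleted RNA in Cy5 (camera adjusted p = 0.21). It was -0.14 with that RNA in Cy3 (camera adjusted p = 0.0144). Different stretches of intestine cannot be told apart from an effect on the genes themselves, as 0 of 17 region genes are among the 100. The median of -0.34 over the 73 genes whose days differ by at most 1 says nothing of a difference shared by both days. For the 1 RNA pair of day 5, fewer crypts in the deleted preparation are argued against. There the 100 genes had a median of -0.27 (SE 0.03 over genes) while the cell cycle list was at 0.03 (SE 0.02) and the Paneth cell list at 0.13 (SE 0.12). On day 3 this explanation cannot be told apart from an effect on the genes themselves, since the 100 genes were at -0.35 (SE 0.08), the cell cycle list at -1.10 (SE 0.03) and the Paneth cell list at -1.28 (SE 0.08). Fewer stem cells and lower expression within them both stay open as hypotheses on either day.

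Stroma genes were higher after deletion on day 5. Carry-over of all tissue under the epithelium is argued against by genes outside the fixed lists, as endothelial genes had a median of 0.25 (SE 0.15, 6 genes) and smooth muscle genes -0.13 (SE 0.10, 4 genes) against 2.14 (SE 0.76, 4 genes) for matrix fibroblast genes. Single values on day 5 were 3.61 for Ccdc80, 2.73 for Fstl1, 1.55 for Col6a3, 0.29 for Col4a1 and 3.09 for Cd34, a gene of endothelium that fibroblasts also express. Carry-over of a part of that tissue, of fibroblasts alone, or a change within fibroblasts, stays open, as the test asked only about all of it together.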

How the results depend on the processing

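One alternative, the fit over genes tested in both comparisons, was chosen after seeing the data; it gave 2427 calls for the day difference against 4410 and left both other counts at 0. Unless stated, the cause of a difference was not tested. No paired analysis was possible because the numbers in the labels mark arrays of 1 RNA pair or separate sorts, and within an array both RNAs are already compared directly; slide and RNA pair coincide. With the RNA pair as a random block (within-pair correlation 0.659) calls numbered 15 in the sorts, 129 in the deletion, 2148 between the days and 2 in both comparisons. The sorts fitted alone gave 65. The range over left-out RNA pairs was 0 to 117 in the sorts, 0 to 6070 in the deletion (1181 without day 3) and 0 to 73 in both, where the lone pair is assumed to vary like the rest; the day difference could not be fitted without a sort or day. Day calls were 72 on processed signals, 0 with median centring, 1103 on the series matrix, 2108 with offset 10, 2783 and 2716 with Cy5 and Cy3 orientations alone, and 1278 when also 2-fold.

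Genes 2-fold higher and lower on every array of the sorts (3 and 14) became 17 and 39 at 1.5-fold, 0 and 6 at 3-fold, 44 and 127 on processed signals, 24 and 59 on the series matrix and 9 and 33 without background subtraction. The higher count was 5 and 9 in the Cy5 and Cy3 orientations and 1 with median centring, the lower 9 with probe means, and over left-out sorts they ranged from 3 to 17 and 15 to 59. For the deletion (12 and 10) they became 65 and 54 at 1.5-fold, 5 and 1 at 3-fold, 50 and 35 on processed signals, 29 and 23 on the series matrix and 26 and 20 in Cy5, with 18 lower in Cy3 and 4 higher with median centring. Over left-out days they ranged from 182 to 274 and 113 to 271, since fewer arrays must pass.

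With an estimated correlation the lists called were 0 in the sorts, 0 in the deletion and 0 between the days. The crypt base stem cell list then no longer passed at 0.75 (adjusted p = 0.419) and -0.59 (adjusted p = 0.621); it passed in 18 of 19 settings each, over 0.48 to 1.02 and -0.76 to -0.38. Lists called were 8 in the sorts with both RNAs above background, and 11 to 19 in the deletion over left-out pairs. Without day 3 the deletion medians turned to 0.13 for Paneth cells, -0.0404 for T cells, -0.37 for enterocytes and -0.36 for tuft cells, and to 0.03 for the cell cycle, -0.15 for goblet cells, -0.03 for the BMP pathway, 0.13 for mast cells, 0.14 for ER stress, 0.03 for endothelium, -0.06 for neurons and glia and -0.0037 for aryl hydrocarbon receptor targets. Without day 5 they turned to -0.11 for regenerating epithelium, 0.11 for enteroendocrine cells, -0.05 for aryl hydrocarbon receptor targets and -0.09 for the imprinted cluster, and Sis was 0.31. Without sort 1 the sort medians turned to -0.06 for the cell cycle, 0.01 for the Notch pathway, 0.0020 for Paneth cells, 0.0005117 for regenerating epithelium, 0.0015 for myeloid cells, 0.02 for stroma and 0.02 for the pancreas, and without sort 2 to 0.0046 for immediate early genes. Without sort 1 the tuft cell median was -0.0432, but the direction camera gave turned and did not pass (camera adjusted p = 0.769). The 100 genes highest in GFPhi lay below 0 throughout, from -0.39 to -0.0381, and passed in 19 of 21 settings, missing at -0.0381 in Cy5 (p = 0.21) and at -0.33 with an estimated correlation (p = 0.322). The 100 lowest passed in 0 of 21, with 0.0079 for 50 genes, -0.0094 on processed signals, -0.10 in Cy3, -0.16 with median centring and -0.079 to 0.159 over left-out pairs. The r of both comparisons was -0.0535 in Cy5, -0.0237 in Cy3, -0.03 with median centring and -0.176 to -0.0718 over left-out pairs.

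Among values of named genes, 4790 kept direction and side of the threshold, 313 passed newly, 12 no longer passed, and 66 changed sign, 65 of them with no call before or after. These 66 belong to 45 of 296 values, and in 21 of the 45 the sign changed only with an RNA pair left out, such as Lyz1 at 0.39 and Mki67 at 0.09 in the deletion without day 3. For lists 1326 were kept, 40 passed newly, 87 no longer passed, and camera's direction turned in 60 without a call and in 5 with one. The sort arrays, with 35.5% to 44.6% of spots well above background, limit dim genes most.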

Other observations

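No test in this part was chosen after its result was seen, though the choice to set the 2 comparisons side by side by list was. Some groups had opposite signs in the sorted cells and after deletion, beyond the stem cell lists. Cholesterol synthesis genes had a median of -0.17 in GFPhi against GFPlo, with 19 of 20 lower, and of 0.41 after deletion, with 21 of 21 higher. For Msmo1 the ratios were -0.61 and -0.82 in the sorts and 0.69 and 0.80 on the 2 days. Antimicrobial and acute phase genes were at -0.31 over the 8 measured in the sorts and at 0.87 over the 17 measured in the deletion. The 8 had deletion medians of 0.30 on day 3 and 0.41 on day 5, and the 17 had 0.29 and 1.22. MHC class II genes were higher in both, at 0.46 and 0.62, the latter made up of 1.05 on day 3 and 0.10 on day 5. H2-DMa was at 0.37 in GFPhi and 0.42 after deletion. Camera called these 3 lists in each comparison with the preset correlation, and the adjusted p was 0.419 to 0.430 in the sorts and 0.621 in the deletion with an estimated correlation.

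The genes around Ascl2 in its imprinted cluster did not pass camera as a list in either comparison. They were at -0.17 in the sorts, with 9 of 12 lower (camera adjusted p = 0.106), and at 0.0056 after deletion, with 8 of 16 lower (camera adjusted p = 0.911). In the sorts 3 members passed adjusted over the list alone, Kcnq1 at 0.68 and Cd81 at 0.51 as higher and Slc22a18 at -0.54 as lower, while a dimmer Slc22a18 probe was at -0.03. Transcription factors of the crypt and the basic helix-loop-helix family were at -0.0044 and -0.06 (camera adjusted p = 0.382 and 0.292), with Phlda1 at 0.82 and Ets2 at 0.71 in the sorts and Ascl2 in the deletion past the test adjusted over the list alone. Notch pathway genes were at -0.0060 and -0.06 (camera adjusted p = 0.719 and 0.292), and BMP pathway genes at -0.12 and 0.16 (camera adjusted p = 0.363 and 0.292), the latter made up of 0.43 on day 3 and -0.03 on day 5. Targets of p53 were at 0.02 and 0.10 (camera adjusted p = 0.722 and 0.378).

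Further lists that did not pass in the sorts were immediate early and heat shock genes at -0.01, regenerating epithelium at -0.08 (Anxa2, at -0.72, passed adjusted over the list alone), interferon response at -0.08, stroma and smooth muscle at -0.05 and pancreas acinar genes at -0.0067 (Rnase1, at -0.48, passed adjusted over the list alone). After deletion, ER stress and secretory load was at -0.16, aryl hydrocarbon receptor targets at 0.0028, mast cells at -0.17, endothelium at -0.06, enteric neurons and glia at 0.03 and erythroid cells at 0.18. In the sorts 1 to 3 genes of the B and plasma cell, mast cell, endothelium, neuron and glia, and erythroid lists were measured, too few to test.

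Across 10263 genes the means of the 2 sorts, each over 2 dye-swapped arrays, correlated with Pearson's r of 0.610. Single dye-swapped arrays of the same RNA, where the dye effect is not averaged out, correlated at 0.557 in sort 1 and 0.392 in sort 2, where the ratios over genes also had a smaller SD of 0.177 against 0.275.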
